A study of Mus musculus with 6 samples.

How the data were processed

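Gene expression was measured by bulk RNA sequencing in 6 libraries of primary mouse hepatic stellate cells from wild-type liver, 2 in each of 3 groups: untreated cells (Control), cells given TGF-beta, and cells given TGF-beta together with the compound K-80003. Doses and treatment times were not given in the sources used here. Per the labels' protocols, polyadenylated RNA was isolated with oligo(dT) beads, fragmented and primed with random primers, and adaptors were ligated to double-stranded cDNA before PCR. The protocol names no molecular identifiers, so counting intervals and floors cover counting error only.

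The deposited table gave for each gene an integer read count per library, an FPKM value per library, an exonic length and the gene's position. The read counts as the authors deposited them were not normalized. The FPKM values that the authors deposited equalled the count divided by the exonic length and by the library's summed count on the usual FPKM scale, within 0.005 for 100% of the values, so they carried no further scaling between libraries. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1, SAMtools 0.1.19, HTSeq 0.6.1, Cufflinks 2.2.1 and DESeq2 were used with the genome build GRCm39. The notes as used here attach no role or order to these tools. The strand setting of the counting and the annotation release were not given in the sources used here, so counts of genes that overlap on opposite strands, and of near-identical paralogs, are uncertain. Of the genes named, those with a counted gene on the other strand include Aldh1l2, Ccn2, Gclm, Ogn, Plod2, Tgfb3 and Timp1. Coordinates are those of the deposited table on GRCm39, counted from 1.

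The table listed 56691 genes, of which 2639 had no symbol. Summed counts per library ran from 15646093 to 19004144, and 3 counts, the floor used for a gene at 0, corresponded to between 0.158 and 0.192 CPM (counts scaled to a common library total). Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. This left 15987 genes; the genes left out held 0.13% of the counts. Libraries were scaled by TMM. The 3 comparisons were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in a fit to all 6 libraries without a block, with 3 residual degrees of freedom, 3.45 prior degrees of freedom and a common dispersion of 0.038. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. Levels are TMM-scaled CPM as mean ± SD over the 2 libraries of a group, and log2 fold changes carry the SE of the fit. The plan, written before the data were examined, named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for a table that also held counts; as counts were present, edgeR was used and limma became an alternative.

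Also set before the data were examined were the groups, the comparisons, the 34 gene lists, the rule for the genes named and most of the alternatives. The 26 lists of pathways and gene families and 8 lists of cell type markers were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were alternatives. The list of lymphocyte and neutrophil markers had 0 genes among those tested, which left 33 lists. Of 556 list entries, 554 were found in the table. Genes named are 10 tied to the study's title or usual for stellate cell activation (another under this rule is not reported here), the genes with the largest fold changes (8 higher and 8 lower for each of the first 2 comparisons, 4 and 4 for the last), up to 4 members of each list with the smallest p, the 3 most abundant members of each marker list, and the 8 genes with the largest opposing changes. Genes picked for size or opposition had an edgeR adjusted p under 0.05, a mean FPKM of at least 5 in the highest group considered and no predicted or clone name. Those picked for size also had no overlap between the libraries compared. For genes with few counts, the ratio of summed counts is given with an exact 95% binomial interval.

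The correlation of the fold changes of TGF-beta against Control and of K-80003 against TGF-beta alone was set beside 100 simulated draws without any effect that used the same shared TGF-beta libraries. The procedure was tested on simulated counts for TGF-beta against Control over 15610 genes. It recovered 28.4% of 67 genes changed by a log2 fold of 1, 88.7% of 62 changed by 2 and 92.3% of 65 changed by 3, and called 9 unchanged genes. A draw with no changed gene gave 0 calls. Within groups, the 2 libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 20.9, so each library was counted as a replicate. That value was 52.5 within Control and 48.0 within TGF-beta. Between Control and TGF-beta libraries it ran from 43.7 to 95.7, so some libraries of different groups were as close as replicates. The labels do not say whether replicates were separate cultures or animals. Gene-wise p-values therefore measure only the spread between these libraries, which may be technical. Camera at the preset correlation sets the genes of a list against all other genes. Its p-values rest on the spread across genes, not across libraries, however small they are.

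Alternatives were no filter on low counts, a minimum FPKM of 5 in 2 libraries, median-of-ratios and upper-quartile scaling, a fit to only the groups compared, the replicate number as a block, DESeq2 1.42.0, limma with pseudocounts of 1 and 0.1, with quantile or median-of-ratios scaling, without its low-value filter and with plain eBayes, and the omission of each library in turn. Omission leaves a group with 1 library, which is then assumed to vary like the other groups. It also unbalances 2 sets of libraries that deviated together. Control replicate 1, TGF-beta replicate 2 and K-80003 replicate 1 form a set, and the remaining libraries the other. A call lost on omission may therefore reflect this imbalance as well as a weak effect. A test restricted to protein-coding genes was not run because the table gives no biotype. Exonic length came from the deposited table, and transcript GC content from GENCODE M21 (GRCm38), matched by gene identifier without use of its coordinates. The software also included pandas 2.3.3 and the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.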

Results

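Hepatic stellate cells are the vitamin A-storing pericytes of the liver and, once activated by signals such as TGF-beta, the main source of scar collagen in fibrosis. Poly(A) RNA of primary mouse stellate cells was sequenced in 3 groups of 2 libraries each: untreated cells (Control), cells given TGF-beta, and cells given TGF-beta with K-80003 (called the K-80003 group here). The study's title places the work on RXRα, a nuclear receptor that pairs with the retinoic acid, PPAR and LXR receptors, and on the CaMKKβ-AMPKα kinase pathway; no group received K-80003 alone. Summed counts were 15646093 and 16597238 in Control replicates 1 and 2, 18339385 and 17420317 in TGF-beta replicates 1 and 2, and 19004144 and 16459654 in K-80003 replicates 1 and 2. Mitochondrial genes took between 1.16% and 1.73% of the counts, and the 10 most abundant genes between 4.73% and 5.6%. All levels are TMM-scaled read counts, scaled to a common library total and given as CPM, with the SD over n = 2 libraries, changes and differences given for genes and list medians are log2 fold changes, and gene-wise adjusted p-values are from edgeR's quasi-likelihood test. Lists were fixed in advance and tested with camera.

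The comparison of TGF-beta with Control asked what the cytokine changed in these cells. TGF-beta raised genes of the collagen scaffold. Col1a1, which encodes the main chain of type I collagen (ENSMUSG00000001506, GRCm39 chromosome 11, 94827050 to 94843868), went from 1438 ± 27.4 to 4556 ± 531 CPM, a log2 fold change of 1.66 (SE 0.15, edgeR adjusted p = 0.00742). Its partner chain Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) went from 1163 ± 51.6 to 2999 ± 86.8 CPM, a change of 1.37 (SE 0.13, adjusted p = 0.00824). Ccn2, a matricellular growth factor also known as CTGF (ENSMUSG00000019997, chromosome 10, 24471340 to 24474581), rose by 1.23 (SE 0.17, adjusted p = 0.0202). The call of Ccn2 was lost with any library left out, at an adjusted p of 0.0732 and 0.0637 without Control replicates 1 and 2, 0.116 and 0.053 without TGF-beta replicates 1 and 2, and 0.0592 and 0.0651 without K-80003 replicates 1 and 2. Acta2, the smooth muscle actin that marks myofibroblasts (ENSMUSG00000035783, chromosome 19, 34218490 to 34232990), stood at 2515 ± 462 CPM in Control and 5019 ± 680 with TGF-beta. Its log2 fold change of 1.00 (SE 0.19) did not pass the threshold (edgeR adjusted p = 0.0512). Among the other scalings, it did with median-of-ratios scaling in edgeR (0.0498) and under limma with quantile normalization (0.0203).

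The receptor and kinase genes of the title did not pass the test with TGF-beta in edgeR's main fit without a block. Rxra (ENSMUSG00000015846, chromosome 2, 27566452 to 27652969) stood at 303 ± 37.7 CPM in Control and 171 ± 25.7 with TGF-beta, a log2 difference of -0.82 (SE 0.17, adjusted p = 0.07, and 0.0471 with upper-quartile scaling). Camkk2, which encodes CaMKKβ (ENSMUSG00000029471, chromosome 5, 122869233 to 122917472), had a log2 difference of -0.27 (adjusted p = 0.587). The AMPKα genes Prkaa1 (chromosome 15, 5173343 to 5211380) and Prkaa2 (chromosome 4, 104887071 to 104967087) had differences of 0.20 and -0.38 (adjusted p = 0.674 and 0.797). For Prkaa2 the sign turned to 0.22 without Control replicate 1. Timp1, an inhibitor of matrix proteases (ENSMUSG00000001131, chromosome X, 20736405 to 20740974), and Tgfb1 itself (ENSMUSG00000002603, chromosome 7, 25386427 to 25404502) had differences of 1.04 and 0.39 (adjusted p = 0.158 and 0.243). With a replicate block in which the TGF-beta numbers were crossed, chosen after seeing the data, Rxra, Acta2, Timp1 and Tgfb1 were called with TGF-beta, while Camkk2, Prkaa1 and Prkaa2 were not. For the title and activation genes over the 3 comparisons, DESeq2 gained 6 calls and edgeR without the low-count filter gained 5.

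Among the largest rises with TGF-beta were those of Adamtsl2, Ltbp2, Ncam1 and Lox. Adamtsl2, a microfibril-binding protein (chromosome 2, 26969391 to 26998993), rose from 33.2 ± 0.749 to 420 ± 30.5 CPM (3.66, SE 0.16, adjusted p = 0.00282). Ltbp2, a latent TGF-beta binding protein, rose by 3.37, Ncam1, a neural adhesion molecule also found on activated stellate cells, by 3.48, and Lox, the enzyme that crosslinks collagen and elastin (chromosome 18, 52649139 to 52662939), from 129 ± 26.8 to 1022 ± 91.5 CPM (2.99). Pyy, a gut peptide hormone, had 19 counts over the Control libraries and 322 with TGF-beta, a ratio of 16.6 (95% counting interval 10.5 to 28). Among the largest falls, Sprr1a, a protein of the cornified envelope, fell by 4.35 and Tspan8, a tetraspanin, by 4.01. In all, 470 of 15987 genes were called, 170 higher and 300 lower, and 398 of them changed by at least 2-fold. The share that was higher, 36.2%, was 25.9% under limma on log2(FPKM + 1), which has no scaling beyond library size, 32.2% under limma with median-of-ratios scaling and 51.2% with the crossed block. Without TGF-beta replicate 1 there were 47 higher and 42 lower. The count was 186 and 101 without Control replicates 1 and 2, 89 and 102 without TGF-beta replicates 1 and 2, and 218 and 205 without K-80003 replicates 1 and 2. Of the 16 genes with the largest changes, 10 were called with every library left out, and of 39 called genes named as list members, 12 were.

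Among the fixed lists, enzymes that process and crosslink collagen had the smallest camera p with TGF-beta. Of 17 measured, 8 rose, among them Lox, Loxl1 (1.74) and Loxl2 (1.51), and 13 rose when adjusted over the list alone (camera adjusted p = 7e-20, and adjusted p = 0.0589 with an estimated correlation). Of 17 collagens, 7 rose, including Col11a1 (3.51) and Col5a2 (1.43), chains of minor fibrillar collagens, and 9 rose adjusted over the list alone (camera adjusted p = 3.15e-13, adjusted p = 0.194 with an estimated correlation). Of 22 early TGF-beta and SMAD target genes, 6 rose and none fell; Pmepa1, a feedback inhibitor of the pathway, rose by 2.53 and Nox4, a superoxide-producing oxidase, by 2.83. Adjusted over the list alone, 14 rose and 3 fell (camera adjusted p = 3.16e-13, adjusted p = 0.0589 with an estimated correlation). Of 23 non-collagen matrix genes, 5 rose, such as the elastin gene Eln (2.42), and 1 fell, against 7 and 2 adjusted over the list alone (camera adjusted p = 3.62e-05, adjusted p = 0.134 with an estimated correlation). None of 20 contractile genes was called over all genes, although 7 rose adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 2.44e-05, and adjusted p = 0.134 with an estimated correlation). The crosslinking count was 5 without Control replicate 1 or either K-80003 library, 4 without TGF-beta replicate 2, and 3 without Control replicate 2 or TGF-beta replicate 1. The collagen count was 4 without Control replicate 2 or any library of the other groups, and the matrix count was 3 without Control replicate 1, 1 without TGF-beta replicate 2 and 2 without any other library, while the matrix gene that fell was not called without either TGF-beta library.

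TGF-beta lowered genes of fatty acid oxidation and of the quiescent stellate cell. Of 19 fatty acid oxidation and PPAR target genes, 6 fell, and 9 fell adjusted over the list alone (median -0.38, camera adjusted p = 1.12e-06, and adjusted p = 0.186 with an estimated correlation). Cd36, a fatty acid transporter, was among the 6; its call was lost without TGF-beta replicate 1 (edgeR adjusted p = 0.0592) and replicate 2 (0.069). The list's count was 2 and 1 without Control replicates 1 and 2, 0 without either TGF-beta library, and 3 without either K-80003 library. Of 20 quiescent stellate cell genes, 4 fell and 1, Adamtsl2, rose, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.00514, and adjusted p = 0.176 with an estimated correlation). That count of 4 was 2 without Control replicate 1 or K-80003 replicate 1, 1 without Control replicate 2 or K-80003 replicate 2, and 0 without either TGF-beta library. Lrat, the enzyme that makes the retinyl esters stored by quiescent stellate cells, stood at 939 ± 230 CPM in Control and 435 ± 60.4 with TGF-beta (log2 difference -1.11, adjusted p = 0.053). NRF2 antioxidant genes also lay lower as a list (median -0.34, camera adjusted p = 0.00533), with 0 of 16 called and 2 lower adjusted over the list alone (adjusted p = 0.211 with an estimated correlation).

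Markers of other cells moved in the same comparison. All 6 cholangiocyte markers had lower values with TGF-beta; 2 fell, and 5 adjusted over the list alone (median -1.26, camera adjusted p = 4.62e-09, and adjusted p = 0.176 with an estimated correlation). Krt19, a keratin of bile duct and mesothelial cells, went from 162 ± 38.2 to 23.6 ± 5.98 CPM (-2.78, SE 0.26, edgeR adjusted p = 0.00789). Of 8 mesothelial markers 4 were measured, and 3 fell, also adjusted over the list alone (median -1.89, camera adjusted p = 2.57e-08, adjusted p = 0.168 with an estimated correlation). Those that fell were Msln, mesothelin (-1.93), and the keratins Krt8 and Krt18, while Wt1 lay higher (0.852) and was not called. The cholangiocyte count was 1 without Control replicate 2 or any library of the other groups, and the mesothelial count was 1 without either TGF-beta library. Of 11 sinusoidal endothelial markers, 2 fell and 1 rose, against 4 and 1 adjusted over the list alone (median -0.49, camera adjusted p = 0.00109, and adjusted p = 0.186 with an estimated correlation). Clec4g, a lectin of sinusoidal endothelium, fell by 3.98; the number that fell was 1 without Control replicate 2 or TGF-beta replicate 1, and the 1 that rose was not called without any library of the TGF-beta or K-80003 groups. Of 7 portal fibroblast markers 4 were measured, and 2 rose and 0 fell, against 2 and 1 adjusted over the list alone. As a list they lay higher (median 0.69, members from -1.6 to 1.99, camera adjusted p = 0.0235, and adjusted p = 0.213 with an estimated correlation). The list did not pass without Control replicate 2. Stellate identity, hepatocyte and macrophage markers did not pass (camera adjusted p = 0.235, 0.0877 and 0.952).

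Other lists passed camera with TGF-beta, but with few called members, and each was lost with an estimated correlation and with at least 1 library left out. Higher were TGF-beta ligands, receptors and SMADs (camera adjusted p = 0.038, 0.386 without Control replicate 2 and 0.16 without TGF-beta replicate 2, adjusted p = 0.544 with an estimated correlation). YAP and TEAD targets were higher too (camera adjusted p = 0.00386, 0.0526 without Control replicate 2, adjusted p = 0.176 with an estimated correlation). So were PI3K and growth factor receptor genes (camera adjusted p = 0.0204, 0.425 without Control replicate 2 and 0.202 without TGF-beta replicate 2, adjusted p = 0.505 with an estimated correlation), with the growth factor Igf1 up by 3.11. Glycolysis genes (camera adjusted p = 0.0328, 0.212 without Control replicate 1 and 0.117 without TGF-beta replicate 1, adjusted p = 0.334 with an estimated correlation) and stress response genes (camera adjusted p = 0.00408, 0.138 and 0.117 without the same libraries, adjusted p = 0.505 with an estimated correlation) were the remaining higher lists. Lower were cell cycle genes (camera adjusted p = 0.00741, 0.0539 without Control replicate 2 and 0.0833 without TGF-beta replicate 2, adjusted p = 0.236 with an estimated correlation) and interferon-stimulated genes (camera adjusted p = 0.00606, 0.0876 and 0.0632 without the same libraries, adjusted p = 0.243 with an estimated correlation). The lists that did not pass were matrix proteases (camera adjusted p = 0.0841), RXR and partner receptors (0.0768), retinoic acid and LXR targets (0.336), CaMKK and AMPK genes (0.7), cytokines and NF-kB targets (0.0768), respiratory chain (0.453), cholesterol synthesis (0.0696), fatty acid synthesis (0.656), p53 targets (0.316), autophagy (0.917) and reference genes (0.369). For matrix proteases the median (-0.01) and mean (0.22) differed in sign, and the test pointed up. For fatty acid synthesis the median (-0.000348) and mean (0.05) differed too. Of 33 lists, 19 passed camera, 11 higher and 8 lower, 0 passed with an estimated correlation and 18 passed fry. For early TGF-beta targets and contractile genes the estimated correlation (-0.027 and -0.0035) lay below the preset 0.01. A correlation above the preset therefore does not account for the loss of those lists. Camera with an estimated correlation uses the 3 residual degrees of freedom. With a preset correlation it takes far more, from the number of genes. For contractile genes the unadjusted camera p went from 5.18e-06 to 0.0156. In any comparison, a list lost with an estimated correlation need not have correlated genes.

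**Figure D1:**
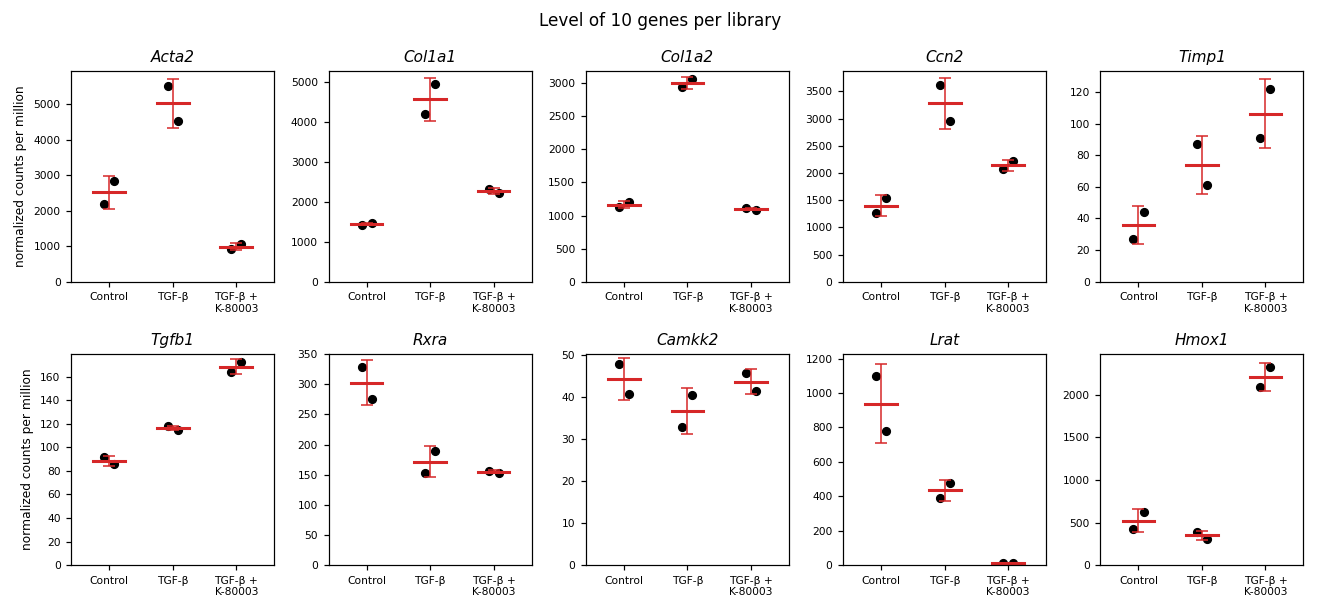
TMM-scaled CPM of 10 genes in each library (points), with bars for the mean and SD of the 2 libraries of each group. Col1a1 and Col1a2 stood at 4556 and 2999 CPM with TGF-beta and at 2273 and 1101 with K-80003 added, and Lrat at 435 and 11.7.

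The comparison of TGF-beta with K-80003 against TGF-beta alone asked what the compound changed in cells that also received the cytokine. Adding K-80003 lowered both the contractile marker and type I collagen. Acta2 fell from 5019 ± 680 to 993 ± 94.7 CPM (-2.34, SE 0.20, edgeR adjusted p = 0.00149) and Col1a2 from 2999 ± 86.8 to 1101 ± 15.4 (-1.45, SE 0.13, adjusted p = 0.00178). Col1a1 fell from 4556 ± 531 to 2273 ± 69.1 CPM (-1.0, SE 0.14, adjusted p = 0.00833), a call lost without K-80003 replicate 1 (0.0871) and replicate 2 (0.111) and under limma with quantile normalization (0.104). Ccn2 (-0.62, adjusted p = 0.0783), Timp1 (0.52, adjusted p = 0.37), Tgfb1 (0.53, adjusted p = 0.0614, and 0.0397 under limma with quantile normalization), Rxra (-0.15, adjusted p = 0.699), Camkk2 (0.25, adjusted p = 0.467), Prkaa1 (0.10, adjusted p = 0.783) and Prkaa2 (0.54, adjusted p = 0.492) were not called. Of these, Ccn2, Timp1, Tgfb1 and Prkaa2 were called with the crossed block.

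The steepest falls with K-80003 included the vitamin A-storage enzyme of stellate cells. Lrat (chromosome 3, 82799886 to 82811280) went from 435 ± 60.4 to 11.7 ± 0.962 CPM (-5.22, SE 0.26, adjusted p = 0.000424). Igfbp3, a carrier of insulin-like growth factors, went from 718 ± 66.9 to 26.6 ± 1.94 CPM (-4.75), Cdh3, P-cadherin, from 60.4 ± 7.32 to 1.09 ± 0.203 (-5.79), and Ogn, the matrix proteoglycan osteoglycin, from 125 ± 2.06 to 3.49 ± 0.0406 (-5.16). Among the steepest rises were Star, the protein that carries cholesterol into mitochondria for steroid synthesis (chromosome 8, 26296583 to 26306010), from 9.87 ± 0.687 to 157 ± 5.85 CPM (3.99, SE 0.16, adjusted p = 0.000215), and Cth, the cysteine-producing enzyme of transsulfuration (3.18). Cyp1a1, the classical target of the aryl hydrocarbon receptor (chromosome 9, 57595211 to 57611107), stood at 476 ± 38.1 CPM in Control, 109 ± 7.5 with TGF-beta and 1059 ± 2.82 with K-80003 (3.28 against TGF-beta). Hmox1, heme oxygenase (chromosome 8, 75820249 to 75827217), rose from 350 ± 55.0 to 2211 ± 165 CPM (2.66, adjusted p = 0.00158). In all 1616 genes were called, 445 higher and 1171 lower, 1197 of them by at least 2-fold, and the share that was higher, 27.5%, was 39.3% under limma on log2(FPKM + 1), 27.8% under limma with median-of-ratios scaling and 46.6% with the crossed block. The count was 865 and 877 without TGF-beta replicates 1 and 2, and 500 and 451 without K-80003 replicates 1 and 2. All 16 genes with the largest changes were called with every library left out, and of 83 called genes named as list members, 49 were.

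K-80003 lowered the contractile and matrix lists together. Of 20 contractile genes, 13 fell and none rose, and 15 fell adjusted over the list alone (median -1.17, camera adjusted p = 4.65e-18); Lmod1, which nucleates actin filaments in smooth muscle, fell by 2.84 and the myosin light chain Myl9 by 2.86. Of 23 non-collagen matrix genes, 10 fell, and 14 adjusted over the list alone (median -0.92, camera adjusted p = 1.9e-15), including Eln (-3.01), the proteoglycan Lum (-2.52) and Tgfbi (-2.62). Of 17 crosslinking enzymes, 10 fell, and 12 adjusted over the list alone (median -0.98, camera adjusted p = 1.62e-11), such as Plod2, which hydroxylates collagen lysines (-2.06), and Loxl1 (-1.53). Of 17 collagens, 9 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone (median -1.0, camera adjusted p = 8.08e-11, adjusted p = 0.186 with an estimated correlation); Col3a1 fell by 2.67 and Col8a1 by 3.26. Of 22 early TGF-beta targets, 8 fell and 1 rose, against 10 and 2 adjusted over the list alone (median -0.34, camera adjusted p = 0.000467, adjusted p = 0.0789 with an estimated correlation). Of 18 TGF-beta ligands, receptors and SMADs, 6 fell and 1 rose, against 7 and 2 adjusted over the list alone (median -0.30, camera adjusted p = 0.00268, adjusted p = 0.479 with an estimated correlation), with the ligands Tgfb2 (-2.94) and Tgfb3 (-2.56) among those that fell. Without K-80003 replicates 1 and 2, in that order, the numbers that fell were 7 and 6 contractile genes, 5 and 4 collagens, 6 and 5 crosslinking enzymes, 2 and 4 early targets, and 2 and 2 ligands and receptors. Early targets that fell were 4 and 5 without TGF-beta replicates 1 and 2, ligands and receptors 3 without TGF-beta replicate 2; the early target and the ligand-list gene that rose were not called without any library of these groups, and the collagen that rose was lost without TGF-beta replicate 1 or either K-80003 library.

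Genes of quiescence and retinoid handling fell as well. Of 20 quiescent stellate cell genes, 11 fell and 1 rose, against 13 and 2 adjusted over the list alone (median -0.94, camera adjusted p = 8.33e-15); besides Lrat these were led by Adamtsl2 (-2.72), the collectin Colec11 (-3.11) and the endothelin receptor Ednrb (-2.19). The 1 that rose was not called without TGF-beta replicate 2 or K-80003 replicate 2. Of 10 stellate identity markers, 8 of which also stand in the quiescence list, 7 fell and 9 adjusted over the list alone (median -1.09, camera adjusted p = 1.93e-12), among them the nerve growth factor receptor Ngfr (-2.64) and the pericyte marker Rgs5 (-2.02). That count was 4 without either K-80003 library. Of 14 retinoic acid and LXR targets, 6 fell, and 8 fell and 1 rose adjusted over the list alone (median -1.11, camera adjusted p = 8.76e-06, adjusted p = 0.0594 with an estimated correlation), including Cyp26b1, which degrades retinoic acid (-2.85). Without K-80003 replicate 2, 3 fell. The RXR and partner receptor genes did not pass (camera adjusted p = 0.575), nor did CaMKK and AMPK genes (0.607).

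Cell cycle, inflammatory and fatty acid oxidation genes were also lower with K-80003. Of 30 cell cycle genes, 26 fell and none rose, and 28 fell adjusted over the list alone (median -1.78, camera adjusted p = 1.46e-37), such as the topoisomerase Top2a, from 73.8 ± 6.06 to 12.8 ± 0.71 CPM (-2.53, edgeR adjusted p = 0.000533), the spindle motor Kif11 (-2.99) and the replication helicase subunit Mcm5 (-1.97). Of 21 cytokines, chemokines and NF-kB targets, 12 fell and 1 rose, against 15 and 1 adjusted over the list alone (median -1.22, camera adjusted p = 5.5e-11, adjusted p = 0.0594 with an estimated correlation), including the monocyte attractant Ccl2 (-2.98) and the adhesion molecules Vcam1 (-1.81) and Icam1 (-1.41). Of 22 interferon-stimulated genes, 10 fell, and 14 fell and 1 rose adjusted over the list alone (median -0.93, camera adjusted p = 2.92e-09, adjusted p = 0.0667 with an estimated correlation), with the GTPase Gbp2 at -2.42 and Ifit3 at -2.31. Of 19 fatty acid oxidation and PPAR targets, 6 fell, and 11 adjusted over the list alone (median -0.65, camera adjusted p = 4.26e-07, adjusted p = 0.167 with an estimated correlation), with the lipase inhibitor Angptl4 at -3.83 and Cd36 at -1.53. Without K-80003 replicates 1 and 2, in that order, the numbers that fell were 16 and 16 cell cycle genes, 6 and 5 cytokines, 3 and 3 interferon-stimulated genes, and 3 and 3 fatty acid genes.

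Stress response lists moved the other way. Of 16 NRF2 antioxidant genes, 9 rose and none fell, and 10 rose adjusted over the list alone (median 0.96, camera adjusted p = 1.15e-12). Nqo1, a quinone reductase, went from 184 ± 5.49 to 728 ± 37.1 CPM (1.99, SE 0.14, edgeR adjusted p = 0.000887), and Srxn1 (1.62) and the glutathione synthesis gene Gclm (1.58) rose with Hmox1. Of 19 unfolded protein and integrated stress response genes, 12 rose, and 16 adjusted over the list alone (median 0.86, camera adjusted p = 3.35e-14, adjusted p = 0.186 with an estimated correlation), including Trib3 (1.95), Atf3 (1.81), the glutathione-degrading enzyme Chac1 (1.80) and asparagine synthetase Asns (1.52). The antioxidant count was 5 without TGF-beta replicate 1 and 4 and 5 without K-80003 replicates 1 and 2; the stress response count was 5 without TGF-beta replicate 2, and 5 and 4 without K-80003 replicates 1 and 2.

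Markers of other cells did not move alike with K-80003. Of 11 sinusoidal endothelial markers, 4 rose and 1 fell, against 5 and 1 adjusted over the list alone (median 0.63, camera adjusted p = 0.033, 0.149 without TGF-beta replicate 1, and adjusted p = 0.251 with an estimated correlation); 0 rose without any library of the TGF-beta or K-80003 groups. Macrophage markers lay lower (median -0.81, camera adjusted p = 0.0291, adjusted p = 0.186 with an estimated correlation). Of 8 measured, 1 fell, and 5 adjusted over the list alone. Hepatocyte (camera adjusted p = 0.509), cholangiocyte (0.245), mesothelial (0.13) and portal fibroblast markers (0.296) did not pass, although 8 of 10 hepatocyte markers had their highest count in K-80003 replicate 2. YAP and TEAD targets were lower (median -0.42, camera adjusted p = 0.0378, 0.0573 without TGF-beta replicate 2 and 0.0997 without K-80003 replicate 2, adjusted p = 0.186 with an estimated correlation). Not past the threshold were matrix proteases (camera adjusted p = 0.0528), glycolysis (0.6), respiratory chain (0.6), cholesterol synthesis (0.314), fatty acid synthesis (0.142), p53 targets (0.491), autophagy (0.296), PI3K and growth factor receptor genes (0.113) and reference genes (0.857). For reference genes the median (0.02) and mean (-0.04) differed in sign. Of 33 lists, 18 passed camera, 3 higher and 15 lower, and 20 passed fry. With an estimated correlation 7 passed: cell cycle, contractile, non-collagen matrix, quiescent, NRF2, stellate identity and crosslinking genes.

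**Figure D2:**
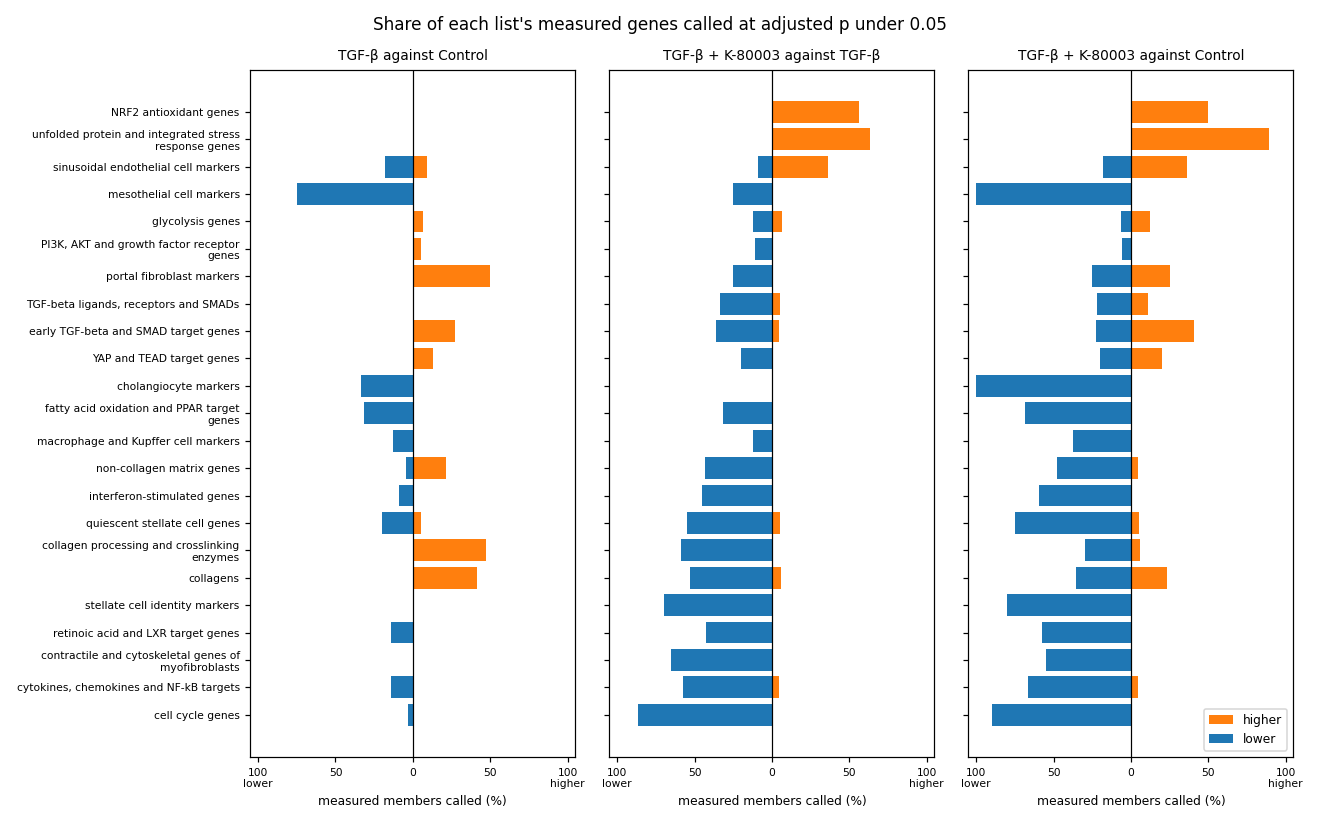
Percentage of the measured members of each fixed list that were called higher or lower by edgeR at an adjusted p under 0.05, with a panel per comparison. With K-80003 against TGF-beta alone, 26 of 30 cell cycle genes and 13 of 20 contractile genes were lower, and 12 of 19 stress response genes were higher.

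The comparison of the K-80003 group with Control showed how far cells given both agents stood from untreated cells; it does not separate the agents. Col1a2 was not told apart from Control, at 1101 ± 15.4 against 1163 ± 51.6 CPM (-0.08, SE 0.13, edgeR adjusted p = 0.753), and Ccn2 (0.61, adjusted p = 0.0557, and 0.0294 under limma with quantile normalization) was not called. Acta2 was lower than in Control (-1.34, SE 0.19, adjusted p = 0.00557, and 0.0589 without K-80003 replicate 1). Col1a1 was higher (0.66, adjusted p = 0.0248), a call lost without Control replicates 1 and 2 (0.0751 and 0.0698) and K-80003 replicates 1 and 2 (0.177 and 0.15), and under limma with median-of-ratios scaling (0.0656) or quantile normalization (0.08). Rxra was lower (-0.97, adjusted p = 0.0127, 0.104 and 0.118 without K-80003 replicates 1 and 2). Tgfb1 was higher (0.93, adjusted p = 0.00638, 0.0603 and 0.0788 without the same libraries), as was Timp1 (1.57, adjusted p = 0.0168, 0.0547 without Control replicate 1 and 0.101 without K-80003 replicate 2). Camkk2 (-0.02, adjusted p = 0.959), Prkaa1 (0.30, adjusted p = 0.249) and Prkaa2 (0.16, adjusted p = 0.835) were not called. Ccn2 and Prkaa1 were called with the crossed block. The sign of Camkk2 turned without Control replicate 1 (0.10) and without K-80003 replicate 2 (0.05), and that of Prkaa2 without Control replicate 2 (-0.29) and without K-80003 replicate 1 (-0.18).

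Among the largest differences from Control, Cth (3.81), Ccn4, a matricellular protein of the WNT pathway (3.45), the mitochondrial folate enzyme Aldh1l2 (3.38, it overlaps Nopchap1 on the other strand) and Bcat1, a branched-chain aminotransferase (3.34), led the higher genes. Lower were Lrat (-6.33), Shisa2 (-6.44), and the protease Mmp7, with 2 counts over the K-80003 libraries and 252 in Control, a ratio of Control to K-80003 of 137 (95% counting interval 37.5 to 1140). The methyltransferase Inmt had 11 and 951 counts, a ratio of 94 (52.3 to 189). In all 2758 genes were called, 886 higher and 1872 lower, and 1941 differed by at least 2-fold. The share that was higher, 32.1%, was 50.3% with the crossed block. The count was 1733 without Control replicate 2, and 1011 and 996 without K-80003 replicates 1 and 2. All 8 genes with the largest differences were called with every library left out, and of 97 called genes named as list members, 69 were.

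Against Control, cells given both agents had lower cell cycle and quiescence genes and higher stress response genes. Of 30 cell cycle genes, 27 were lower, and all 30 adjusted over the list alone (median -1.91, camera adjusted p = 6.83e-35), and of 20 quiescence genes 15 were lower and 1 higher, against 16 and 1 adjusted over the list alone (median -1.68, camera adjusted p = 4.14e-15). These 2 lists were the ones that passed with an estimated correlation, of 13 of 33 that passed camera, 2 higher and 11 lower. By fry, 16 of 33 passed. Of 19 stress response genes, 17 were higher, and 18 adjusted over the list alone (median 1.14, camera adjusted p = 5.68e-16, adjusted p = 0.201 with an estimated correlation), such as Asns (2.11) and the mitochondrial folate enzymes Mthfd2 (1.85) and Shmt2 (1.76). Of 16 NRF2 genes, 8 were higher, and 8 adjusted over the list alone (median 0.65, camera adjusted p = 2.86e-05, adjusted p = 0.11 with an estimated correlation). Of 19 fatty acid oxidation genes, 13 were lower, and 14 adjusted over the list alone (median -0.82, camera adjusted p = 4.25e-12, adjusted p = 0.0917 with an estimated correlation). Without K-80003 replicates 1 and 2, in that order, the counts were 8 and 8 quiescence genes, 10 and 6 stress response genes, 4 and 5 NRF2 genes, and 7 and 7 fatty acid genes. Fatty acid genes numbered 8 without Control replicate 2, and the 1 quiescence gene that was higher was lost without either K-80003 library.

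Contractile, matrix, inflammatory and retinoid genes were below Control too. Of 20 contractile genes 11 were lower, and 11 adjusted over the list alone (median -0.87, camera adjusted p = 1.67e-06), and of 23 non-collagen matrix genes 11 were lower and 1 higher, against 12 and 3 adjusted over the list alone (median -0.59, camera adjusted p = 6.19e-05). Of 21 cytokines 14 were lower and 1 higher, against 16 and 1 adjusted over the list alone (median -1.60, camera adjusted p = 6.49e-11), with Cxcl5 at -5.18. Of 22 interferon-stimulated genes 13 were lower, and 16 adjusted over the list alone (median -1.24, camera adjusted p = 6.49e-11). Of 14 retinoic acid and LXR targets 8 were lower, and 9 lower and 1 higher adjusted over the list alone (median -1.02, camera adjusted p = 3.57e-05), with Cyp26b1 at -4.54 and the lipid carrier Apoe at -3.22. Each of these 5 lists had adjusted p = 0.078 with an estimated correlation. Without K-80003 replicates 1 and 2, in that order, the lower genes numbered 5 and 6 contractile, 7 and 8 cytokine, and 4 and 3 retinoid and LXR genes, and interferon-stimulated genes numbered 7 without K-80003 replicate 2. Collagens went both ways, 4 higher and 6 lower, and the same adjusted over the list alone, with a median of 0.13, a mean of -0.28 and a test that pointed down (camera adjusted p = 0.443). The higher collagens numbered 1 and 0 without Control replicates 1 and 2, 2 without either TGF-beta library and 0 without either K-80003 library.

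Markers of stellate, duct and mesothelial cells were also below Control. Of 10 stellate identity markers 8 were lower, and 8 adjusted over the list alone (median -1.48, camera adjusted p = 1.22e-10, adjusted p = 0.0668 with an estimated correlation), and 5 without either K-80003 library. All 6 cholangiocyte markers were lower, also adjusted over the list alone (median -2.02, camera adjusted p = 3.99e-06, adjusted p = 0.188 with an estimated correlation), and 3 without K-80003 replicate 2. All 4 mesothelial markers were lower, also adjusted over the list alone (median -2.12, camera adjusted p = 1.17e-06, adjusted p = 0.13 with an estimated correlation). Lists that did not pass were crosslinking enzymes (camera adjusted p = 0.999), matrix proteases (0.722), early TGF-beta targets (0.239), TGF-beta ligands (0.326), RXR partners (0.722), CaMKK and AMPK genes (0.689), glycolysis (0.548), respiratory chain (0.999), cholesterol synthesis (0.953), fatty acid synthesis (0.187), p53 targets (0.314), autophagy (0.548), YAP targets (0.999), PI3K genes (0.999) and reference genes (0.675). Hepatocyte (0.88), macrophage (0.109), endothelial (0.999) and portal fibroblast markers (0.793) did not pass either. Median and mean differed in sign for RXR partners (0.05 and -0.19), glycolysis (-0.12 and 0.05), autophagy (-0.05 and 0.04) and endothelial markers (0.32 and -0.62). The test pointed up where median and mean were negative for respiratory chain, cholesterol synthesis, YAP, PI3K and portal fibroblast lists, and down where both were positive for hepatocyte markers.

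A last comparison asked whether the changes with K-80003 ran against those with TGF-beta. Of the 170 genes that TGF-beta raised, 77 fell when K-80003 was added, 12 rose further and 81 were not called, and of the 170, 83 were still above Control and 21 below it. Of the 300 genes that TGF-beta lowered, 23 rose with K-80003, 76 fell further and 201 were not called, and of the 300, 268 were still below Control and 6 above it. The largest opposing changes were those of Ltbp2 (3.37 with TGF-beta, then -4.61), Cdh3 (1.16, then -5.79), Rgs4, a brake on G protein signalling (1.93, then -4.65), Adamtsl2 (3.66, then -2.72) and Eln (2.42, then -3.01). The TGF-beta call of Cdh3 was lost without any of the 6 libraries.

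Both comparisons contain the TGF-beta libraries with opposite sign, so chance alone makes them run against each other. Across 15987 genes, which are not independent replicates, fold changes taken as differences of mean log2 CPM had Pearson's r of -0.0962, Spearman's rho of -0.0890 and a covariance of -0.0408. With edgeR's own fold changes r was -0.101. In 100 simulated draws without any effect, r averaged -0.499 (SD 0.013) and the covariance -0.0723 (SD 0.0029), a difference in covariance of 0.0316. With the spread taken from a fit with a crossed replicate block, chosen after seeing the data, the simulated covariance was -0.0331 and the difference -0.00769. For r the observed value lay above the simulated one by 0.403 with the first spread and 0.404 with the second, but a difference of correlations does not measure a shared effect. In these draws the libraries varied independently. Here the differences between the 2 libraries of a group were shared by the groups, with the TGF-beta numbers crossed. Such differences partly cancel in group means, so the first spread is too wide for these fold changes. The difference in covariance had the other sign with the second spread, which was chosen after seeing the data. No shared or opposing effect across all genes was established. Independent lists of the same sizes would share 12.5 genes raised then lowered, 8.35 lowered then raised, 4.73 raised in both and 22 lowered in both, against 77, 23, 12 and 76 observed. Part of the excess of opposing calls may come from the shared libraries. A count with a different TGF-beta library in each comparison was not made. The 100 opposing calls numbered 53 and 29 without Control replicates 1 and 2, 28 and 30 without TGF-beta replicates 1 and 2, and 34 and 30 without K-80003 replicates 1 and 2.

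**Figure D3:**
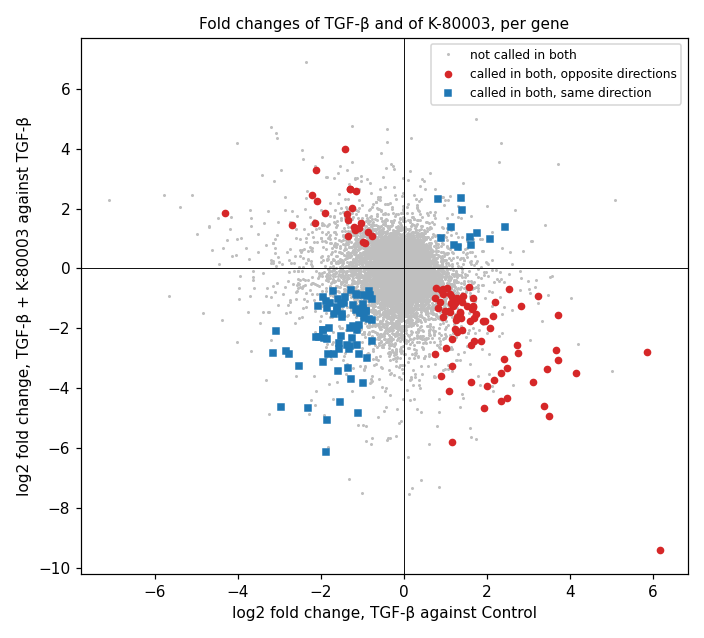
Log2 fold change with K-80003 against TGF-beta alone (vertical axis) plotted against log2 fold change with TGF-beta against Control (horizontal axis) for 15987 genes. Red points are the 100 genes called in opposite directions and blue points the 12 raised and 76 lowered in both, and the correlation of these edgeR fold changes is -0.101 across genes.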

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

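Chosen after the data were seen were upper-quartile scaling, the crossed pairing and the spread of a crossed fit. Against 470, 1616 and 2758 genes called for TGF-beta against Control, K-80003 with TGF-beta against TGF-beta, and K-80003 with TGF-beta against Control, in that order, edgeR gave 465, 1614 and 2762 with median-of-ratios scaling and 476, 1632 and 2751 with upper-quartile scaling. Without the low-count filter it called 1143 and 2492 genes in the first and second comparison, and with a minimum FPKM of 5 it called 210, 965 and 1354, where fewer genes were tested. A fit to only the groups compared, with fewer residual degrees of freedom, called 199 genes for TGF-beta against Control, and DESeq2 called 735. By limma on log2(FPKM + 1) the counts were 371, 1147 and 2072. Limma called 266 genes with a pseudocount of 0.1 and 313 with quantile normalization for TGF-beta against Control. It called 104, 582 and 1463 genes without its filter, 189, 838 and 1240 with a minimum FPKM of 5, and 0, 940 and 1515 with only the groups compared. The share of higher genes with K-80003 against TGF-beta was 27.5% by edgeR, 39.3% by limma and 37.2% with a pseudocount of 0.1, where limma used FPKM without further scaling, and 27.8% by limma with median-of-ratios scaling. The median of all genes in that comparison was 0.101 by limma on unscaled FPKM, 0.121 with the smaller pseudocount and 0.00698 with median-of-ratios scaling. The labels do not say that a replicate number marks a shared animal or day, and within-group differences correlated at -0.636 between Control and TGF-beta, 0.504 between Control and the K-80003 group, and -0.476 between TGF-beta and the K-80003 group, so the numbers were not taken to pair the samples. With the number as a replicate block, edgeR called 40, 792 and 1564 genes and limma 0, 326 and 926; at an unadjusted p under 0.05 limma had 1404 genes for TGF-beta against Control with the block and 1428 with only the groups compared. With the TGF-beta numbers crossed, a pairing chosen after seeing the data, the replicate block called 3708 genes (1900 higher and 1808 lower), 5903 (2749 and 3154) and 7352 (3701 and 3651), gave 1092 opposing calls and gained 10 calls of named genes. With each library left out, counts ran from 89 to 218, from 451 to 1661 and from 996 to 2397. The correlation of the fold changes of TGF-beta and K-80003, -0.101 by edgeR, stayed below 0: it was -0.405 without the filter, -0.00752 with a minimum FPKM of 5, -0.378 by DESeq2, -0.0261 by limma with a minimum FPKM of 5, -0.263 over genes called with TGF-beta and -0.0216 over genes with a mean FPKM of at least 10, and from -0.434 to -0.0906 with a library left out. Opposing calls, 100 by edgeR, numbered 249 without the filter, 61 with a minimum FPKM of 5, 9 with the replicate block, 160 by DESeq2, 66 with a pseudocount of 0.1, 21 by limma without its filter, 49 by limma with a minimum FPKM of 5 and 0 by limma with the replicate block, and from 28 to 53 with a library left out. Camera with an estimated correlation passed 0, 6 and 2 of the pathway lists in the 3 comparisons, against 15, 15 and 10 with the preset correlation, and 0, 1 and 0 of the marker lists, against 4, 3 and 3. Fry passed 14, 16 and 12 pathway lists, and 4 marker lists in each comparison. For K-80003 against TGF-beta, 2 marker lists passed on log2(FPKM + 1), 1 higher and 1 lower, and 1, lower, on log2(FPKM + 0.1). The main test had passed 1 higher and 2 lower. Of 300 list results under other settings, 247 kept their side of the threshold and 53 lost it, and with a library left out 283 of 300 kept it and 17 lost it. Of 4981 values of named genes under other settings, 4438 kept direction and side, 510 lost their call, 32 gained one and 1 changed sign, and with a library left out 1471 of 1806 kept both, 330 lost their call and 5 changed sign. The sign changes were all in uncalled genes. The values of named genes covered those called by edgeR, and the 10 title and activation genes whether called or not. Only uncalled genes of those 10 could therefore gain a call, also with the crossed block. Camkk2 against Control in the K-80003 group, -0.02 by edgeR, was 0.017 with quantile normalization, and ran from -0.155 to 0.0971 with a library left out, with 0.0495 without K-80003 replicate 2. Prkaa2 ran from -0.808 to 0.217 for TGF-beta against Control and from -0.288 to 0.754 for the K-80003 group against Control, with -0.179 without K-80003 replicate 1. Where the settings above name no smaller set of genes or samples, the cause was not tested. Depth limits low genes: 3 counts were 0.158 to 0.192 CPM. By simulation over genes of all levels, 28.4% of those changed by a log2 fold of 1 were recovered for TGF-beta against Control. That simulation did not vary depth, and its libraries varied independently, without the differences that the groups share here.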

Other observations

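Tests of transcript length and GC content were written before their results were seen, and the other tests here were chosen after. Levels of some cell type genes are given here in more detail. Emcn, the endothelial sialomucin endomucin, stood at 4.85 ± 1.9 CPM in Control, 16.5 ± 0.449 with TGF-beta and 37.9 ± 3.34 with K-80003 added (2.96 against Control, edgeR adjusted p = 0.00122), while the endothelial lectin Clec4g went the other way, from 11.7 ± 2.71 to 0.732 ± 0.164 and 0.461 ± 0.237 CPM. Pdgfra, a receptor of fibroblasts and stellate cells, stood at 292 ± 79.0, 141 ± 22.1 and 72.5 ± 10.4 CPM in the same order (-2.01 against Control in the K-80003 group, adjusted p = 0.00308). Of 10 hepatocyte markers, 8 had their highest count in K-80003 replicate 2. Alb had 416 counts there and between 56 and 129 in the other libraries, Cyp2e1 86 and between 0 and 6, Apoa1 75 and between 2 and 18, Ahsg 66 and between 7 and 14, and Ttr 54 and between 4 and 10, and Fgb (34), Cyp3a11 (26) and Serpina1a (21) were highest there too. The exceptions were Apob, with 456 there and between 640 and 3370 in the others, and Hnf4a, with 34 there and between 20 and 149.

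The differences between the 2 libraries of a group were shared by all 3 groups, with the numbers of the TGF-beta libraries crossed: over genes above 10 CPM they correlated at -0.875 between Control and TGF-beta, 0.833 between Control and the K-80003 group, and -0.843 between TGF-beta and the K-80003 group. Exonic gene length, used in place of transcript length, followed them, with Spearman's rho across genes of 0.675 in Control, -0.688 with TGF-beta and 0.698 with K-80003. Yet the mean size of the correlation between groups was 0.85 before and 0.719 after a loess on exonic length. After a loess on GC content it was 0.854. These values argue against GC content or exonic length as the whole cause. Exonic length need not be the length of the transcripts in these cells, so transcript length itself is not settled. What else set the libraries apart stays open, since no label names a batch and no biological explanation was tested.

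Stellate identity markers lay lower with K-80003 than with TGF-beta alone (median -1.09). A lower share of stellate cells should raise the markers of every other cell type alike, but the medians of endothelial (0.63) and cholangiocyte markers (-0.47) differed by 3.23 SE of their difference, the largest of 6 such differences, and those of endothelial and macrophage markers by 2.81, while the other 4, from 0.442 to 1.55, lay within 2 SE. These SEs came from resampling the genes of each list and leave out the spread between libraries, so the comparison of medians cannot decide. Its larger differences also rest on the endothelial list alone. The stellate markers' spread, 5.86 times what their SEs from the fit allow and 3.3 times without Lrat, argues against a lower share as the sole cause. The stellate marker median was no higher than -0.979 under 4 scalings, so the choice among them does not account for it. These scalings differed little, and none of them can see a shift common to all genes. A scaling shift of that kind was therefore not tested. That K-80003 may lower these genes within stellate cells, Lrat among them, stays open as a hypothesis that no test here addressed, beside a change in another cell type, which counts from single cells could tell apart.

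Cholangiocyte markers and 3 of 4 mesothelial markers lay lower with TGF-beta than in Control, and Wt1 higher. Krt8 stood at 356 ± 86.1 CPM in Control and 86.6 ± 11.5 with TGF-beta, and Krt18 at 257 ± 74.8 and 71.0 ± 11.1. A lower share of cholangiocytes should lower their markers by a common factor, but the cholangiocyte markers spread 3.17 times as widely as their SEs allow, and 2.07 times without Krt19, which argues against it as the sole cause. For mesothelial cells the spread was 4.13 times that expected but 0.418 times without Wt1, so a lower share of mesothelial cells cannot be told apart from a change within cells. The test of both shares replaced a pooled test whose value had been seen. The marker median was no higher than -1.58 under 4 scalings, so the choice among them does not account for it. A shift common to all genes cannot be seen by any of them and was not tested. A joint loss of both cell types, which could lower all these markers, stays open beside an effect of TGF-beta within cells.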
